A study of Mus musculus with 2 samples.

How the data were processed

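RNA from primary calvarial osteoblasts of 5-day-old C57BL/6 mice was measured in 2 samples, 1 kept in 1 mM phosphate and 1 in 4 mM phosphate for 6 h. Per the labels' protocols, cells were released with collagenase and dispase, grown for 3 days in medium with 10% serum to 80 to 90% confluence, and deprived of serum overnight before treatment. The added phosphate came from a 0.5 M sodium phosphate stock at pH 7.2, so sodium was added with it. Total RNA (100 ng per sample) was made into biotin-labelled cRNA by the manufacturer's standard procedure and hybridised to Affymetrix mouse arrays, per the labels' protocols. Groups were taken from the sample labels.

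The deposited values are intensity values on a linear scale, 1 per probe set and array, made with the MAS5 algorithm in GCOS 1.4, per the submitters' processing notes. MAS5 subtracts a local background, combines perfect-match and mismatch probes into 1 signal and scales each array by a single factor. The mean signal without the lowest and highest 2% of probe sets was 200.00 on both arrays, as calculated from the deposited values. Such scaling sets the average signal equal, so it hides any change of total mRNA per cell. Dim probe sets are noisy in MAS5 values. Detection calls and probe-level values were not used here.

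The table held 45101 probe sets, of which 64 were manufacturer's controls, kept apart. Of the other 45037, the probe annotation used named 1 gene for 34945, several genes for 932 and none for 9160. Genes were named only from probe sets with 1 gene. Symbols were updated by Entrez identifier against the RefSeq gene table of GRCm38.p6, used for names only. It held the identifiers of 34741 of these probe sets, and 0 symbols changed. This gave 18194 genes. Of 861 entries in the gene lists, 67 had no probe set that named only that gene and were not analysed here.

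Values under the pooled median of both arrays (21.5) were raised to it, and log2 ratios were calculated as phosphate minus control. A probe set was called measured if at least 1 array was above this floor, which held for 24159 probe sets, 20878 of them on both arrays. Each gene took the probe set with the highest mean log2 signal among those naming only it. Where 1 array was at the floor, the ratio is a bound and is written as at least N-fold. With 1 array per group there were no replicates, so genes were counted by size of ratio (2-fold, and 1.5-fold for all of 2 or more probe sets) and no test was run. Depth has no direct counterpart on arrays, and the number of arrays limits the precision. The only measures of error were technical. The log2 ratios of probe sets of the same gene had a standard deviation per probe set of 0.38 where the dimmer signal was between the floor and 100, 0.26 between 100 and 400, and 0.17 above 400.

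Gene lists were fixed before the data were examined, as were the floor, the gene naming rule and the first 9 settings listed as alternatives. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list with at least 4 measured genes was called set apart below percentile 2.5 or above percentile 97.5, which describes these arrays and is no test between conditions. The 35 lists covered phosphate transport and sensing, pyrophosphate and mineralisation regulators, SIBLING and osteocyte genes, osteoblast identity, ERK and immediate early response, FGF ligands and receptors, matrix proteases, collagens, BMP and TGF-beta targets, YAP and SRF targets, Wnt genes, osteoclast regulating factors, cytokines and chemokines, interferon response, unfolded protein and integrated stress response, oxidative stress and metal response, p53 targets, cell cycle, cholesterol biosynthesis, glycolysis and hypoxia, respiratory chain, ribosomal proteins, heat shock chaperones, lysosome and autophagy, insulin and FoxO response, and circadian and glucocorticoid responsive genes. They also covered markers of macrophages and osteoclasts, chondrocytes, adipocytes, endothelium, skeletal muscle, pericytes and mesenchymal progenitors, neural and glial cells, erythroid and mast cells, and reference genes.

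The genes named were set by rule. It took the 12 highest and 12 lowest genes above the floor on both arrays, and the 10 per direction with the largest ratio of their least moved probe set among genes with 2 or more probe sets. It also took the 5 largest bounds per direction, and the 2 highest and 2 lowest members of each list. From the lists on phosphate transport, mineralisation, SIBLING and osteocyte genes and osteoblast identity, any measured member could be named. Fgf23, the macrophage and osteoclast markers Lyz1, Lyz2, Ctsk, Ctss, Csf1r and C1qa, and the members named from the cilium, CREB and NF-kB lists were chosen after their values were seen. Clone-derived names were counted but not printed.

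The other settings tried were no floor, floors at the pooled 35th and 65th percentiles, a pseudocount equal to the floor, centring on the median, quantile normalization, a loess correction on level with span 0.3, the median of all probe sets of a gene, and leaving out probe sets marked for cross-hybridisation. Chosen after seeing the data were a floor at a signal of 100, poly-A spikes set to equal signal, lists without members of the immediate early and cytokine lists, and lists without members above the floor on 1 array only. The steps were tested on 20 simulated array pairs with the spread seen between probe sets of a gene, each with 200 changed genes among a median of 12088 measured. Of genes changed by a log2 ratio of 1.5, 93.7% were found at least 2-fold different, and 96.3% of those changed by 2. With no change simulated, 5.24% of lists were set apart, and a list shifted by 0.4 was set apart in 20 of 20 pairs. The simulated noise was drawn separately for each probe set, so it held no variation shared by the genes of a list. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.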

Results

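Gene expression was measured in primary osteoblasts, the bone-forming cells, isolated from the skull caps (calvariae) of 5-day-old C57BL/6 mice. After a night without serum, the cells spent 6 h in serum-free medium with either 1 mM phosphate, the control, or 4 mM phosphate, both at pH 7.2. Each condition was represented by 1 array, so there was no replicate error, no test between conditions was possible and no p-value is given. The number of arrays limits the precision of every value, and the differences describe these 2 arrays. Of 45037 probe sets other than manufacturer's controls, 22074 (49.0%) on the control array and 22963 (51.0%) on the phosphate array lay above the signal floor of 21.5. The ratio of 3′ to 5′ signal, a sign of RNA integrity, was 1.36 and 1.43 for actin and 0.748 and 0.769 for Gapdh on the control and phosphate arrays.

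The comparison asked which genes osteoblasts express differently within hours of a higher phosphate concentration outside the cell. Of the lists fixed beforehand, the immediate early response and the cytokines and chemokines had the highest medians, 1.65 and 0.95 in log2 ratio. Ptgs2, which encodes the inducible prostaglandin synthase cyclooxygenase-2, was 18.5-fold higher in 4 mM phosphate, with a signal of 184 in the control and 3404 in phosphate. Il6, the gene of the cytokine interleukin-6, lay below the floor in the control and reached 664 in phosphate, which made it at least 30.9-fold higher. Sost, which encodes the Wnt inhibitor sclerostin of osteocytes, had the lowest ratio among genes above the floor on both arrays (log2 ratio −3.17), with signals of 359 and 39.9. Of 17 measured regulators of pyrophosphate and mineralisation, 3 were at least 2-fold higher and 3 at least 2-fold lower, while the osteoblast collagens Col1a1 and Col1a2 differed by log2 ratios of 0.23 and 0.21.

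Of 12241 genes measured above the floor on at least 1 array, 279 were at least 2-fold higher and 358 at least 2-fold lower in 4 mM phosphate. Of these, 239 higher and 316 lower genes were above the floor on both arrays. At 4-fold, counted under the main floor and scaling only, the order turned, with 60 genes higher and 12 lower. The floor limits the ratio a dim gene can reach, and the lower genes were dimmer. Within 1.5-fold lay 80.6% of measured genes. Noise alone, simulated from the spread between probe sets of the same gene, gave a median of 35 genes at least 2-fold higher and 16 lower. It made no allowance for differences between cultures. The noise was added to the second array only, so the simulated split between higher and lower is no fair reference. Its size came from probe sets above the floor on both arrays, and dimmer probe sets may vary more. Where a gene had a second probe set above the floor on both arrays, it pointed the same way for 86 of 90 higher genes (95.6%) and 66 of 78 lower genes (84.6%). Among 5606 genes with 2 or more measured probe sets, 169 had all of them at least 1.5-fold higher and 163 had all of them at least 1.5-fold lower.

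The split between higher and lower genes depended on the floor and the scaling. Higher genes outnumbered lower genes without a floor (2126 against 1841), with the floor at the pooled 65th percentile (183 against 164) or at 100 (156 against 119), and with a pseudocount (216 against 171), and the loess correction left them about equal (299 against 298). Poly-A spikes, bacterial RNAs added to a sample before labelling, were brighter on the phosphate array by a median log2 ratio of 0.46. With these spikes set to equal signal, a choice made after seeing the data, all log2 ratios moved by −0.46 and the counts became 129 genes higher and 1727 lower. Percentiles of gene lists among random lists, given with each list, are relative to genes of like signal and were not altered by this shift.

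**Figure D1:**
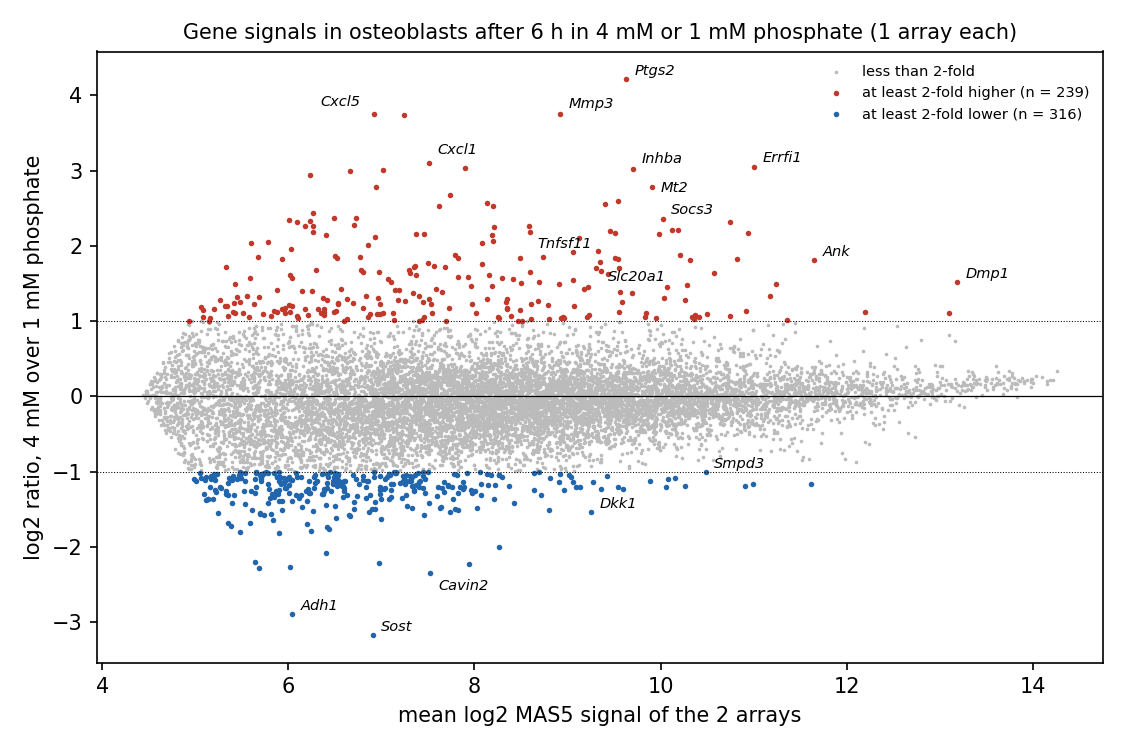
Each point is 1 of the 11184 genes above the floor on both arrays, with its mean log2 signal on the horizontal axis and its log2 ratio of 4 mM over 1 mM phosphate on the vertical axis. Red points mark 239 genes at least 2-fold higher and blue points 316 genes at least 2-fold lower under the deposited scaling, with Ptgs2 highest at 4.21 and Sost lowest at −3.17.

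Among 40 measured genes of the ERK and immediate early response, a set of transcription factors and feedback regulators induced within minutes to hours of a growth signal, 28 were at least 2-fold higher, none was 2-fold lower, and all 40 had log2 ratios above 0. Their median was 1.65, at percentile 100 of random lists. The orphan nuclear receptor genes Nr4a3 and Nr4a1 were 13.4-fold and 8.22-fold higher, and the zinc finger transcription factor gene Egr2 was 7.95-fold higher, with 4.06-fold on its other probe set. Fosl1, a partner of Jun proteins in the AP-1 transcription factor, was at least 14.5-fold higher. Dusp5, encoding a phosphatase that inactivates ERK, was 7.67-fold higher. Klf4 and Jund had the lowest ratios of the list, with log2 values of 0.04 and 0.11. Outside the list, Errfi1, a feedback inhibitor of the EGF receptor, was 8.29-fold higher, and Socs3, an inhibitor of cytokine signalling, was at least 4.69-fold higher on each of 3 probe sets.

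Of 30 measured cytokine and chemokine genes, 15 were at least 2-fold higher and none was 2-fold lower, with a median of 0.95 at percentile 100. The neutrophil-attracting chemokine genes Cxcl5 and Cxcl1 were 13.5-fold and 8.60-fold higher, Cxcl5 from a dim control signal of 33.1. The other probe sets of Cxcl1 had a log2 ratio of 1.49 and, with the control below the floor, one of at least 4.35. The lowest members, Cxcl12 and Ccl3, both had log2 ratios of −0.33, with 0.20 on a dimmer probe set of Cxcl12. Macrophage and osteoclast markers were present on both arrays and as a list lay lower in phosphate. Their median was −0.33 at percentile 0.17, and 16 of 21 were below 0. The macrophage genes Aif1 and Mrc1 had log2 ratios of −0.80 and −0.79, against 1.21 for Cd14, a receptor for bacterial lipopolysaccharide. With the median over all probe sets of a gene, the percentile of this marker list was 6.65.

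Factors that act on osteoclasts, the bone-resorbing cells, had a median of 0.54 at percentile 100, with 7 of 16 at least 2-fold higher and 1 lower. Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, was 4.56-fold higher, and its second probe set had a log2 ratio of 2.66. Tnfrsf11b, encoding osteoprotegerin, the decoy receptor of RANKL, was 3.78-fold higher. Sema3a, a secreted semaphorin, had the lowest ratio of the list at −1.08, although its other probe set gave 0.13. Without the 6 members shared with the immediate early and cytokine lists, a choice made after seeing the data, the median of the remaining 10 was −0.16 at percentile 32.3. The full list had 0.20 with the median of probe sets, and 0.19 without members above the floor on 1 array only.

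Of 14 measured genes of phosphate transport and sensing, 1 was at least 2-fold higher and none was 2-fold lower. Slc20a1, the gene of a sodium-dependent phosphate importer, went from 351 to 1205 (3.43-fold higher). Its other measured probe sets, below the floor in the control, gave lower bounds, the smaller being 0.43 in log2 ratio. Slc20a2, a second importer of this family, and Xpr1, a phosphate exporter, had log2 ratios of −0.16 and −0.07, although a dimmer probe set of Slc20a2 gave 0.54. The list was not set apart, with a median of −0.03, a mean of 0.15 and percentile 61.7. Fgf23, the phosphate-regulating hormone made by bone, was at the floor on both arrays.

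Regulators of pyrophosphate and mineralisation had a median of 0.32 at percentile 99.99, which became 0.13 after quantile normalization, 0.16 after the loess correction and −0.15 with the poly-A spikes as reference. Of 17 measured members, 3 were at least 2-fold higher, 3 were 2-fold lower and 10 lay within 1.5-fold. Enpp1, Phospho1, Abcc6 and Ahsg, the rest of the list, gave no value. They were at the floor on both arrays or had no probe set that named only them. Ank, the transporter gene that supplies the mineralisation inhibitor pyrophosphate to the outside of the cell, went from 1723 to 6020 (3.49-fold higher). Nt5e, encoding the ectonucleotidase CD73, was 3.66-fold higher, with 2.17-fold on its other probe set. Smpd3, a sphingomyelinase needed for normal bone mineralisation, had a log2 ratio of −1.01, with a range of −1.16 to −0.91 over 3 probe sets. Car2, encoding carbonic anhydrase 2, had a log2 ratio of −1.12. Alpl, the alkaline phosphatase that degrades pyrophosphate, and Mgp, an inhibitor of calcification, differed little, with −0.19 and 0.32.

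Among 13 measured genes of SIBLING matrix proteins and osteocytes, 5 were at least 2-fold higher and 2 at least 2-fold lower. The SIBLING genes Dmp1 and Mepe, both expressed in osteocytes, went from 5505 to 15708 and from 1458 to 3680, and the 3 probe sets of Dmp1 had log2 ratios between 1.51 and 2.38. Fam20c, the kinase that phosphorylates SIBLING proteins, was 2.93-fold higher, with log2 ratios from 0.93 to 1.55 over 3 probe sets, and Cd44, a receptor for hyaluronan and osteopontin, was 2.82-fold higher. The osteocyte gene Sost and the Wnt inhibitor gene Dkk1 were the 2 lower members, Dkk1 at −1.53 and −2.31 on its 2 probe sets. The list's median of 0.21 lay at percentile 99.1, became −0.25 with the poly-A spikes as reference and 0.50 with the median of probe sets, and was at percentile 96.8 with the floor at the pooled 35th percentile. Phex and Ibsp, another SIBLING gene, had log2 ratios of 0.21 and 0.11.

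None of 20 measured osteoblast identity genes was 2-fold different, and 19 lay within 1.5-fold. The exception was Tnc, the matrix protein tenascin C, at 0.61, with 1.54 on a dimmer probe set. The osteoblast transcription factor gene Sp7 had a log2 ratio of −0.39 and the parathyroid hormone receptor gene Pth1r −0.24. The list was not set apart at percentile 3.15 with a median of −0.08, but lay below the lower limit under 5 alternatives. These were quantile normalization (percentile 0.15, median −0.20), the loess correction (0.24, −0.17), the median of probe sets (0.22, −0.17), and the floors at the pooled 65th percentile (0.38, −0.12) and at 100 (0.44, −0.12). Of 33 measured collagen and collagen assembly genes, 30 lay within 1.5-fold, the median was 0.08 and the percentile 81.6. The highest was Plod2, a collagen lysyl hydroxylase, at 1.08.

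**Figure D2:**
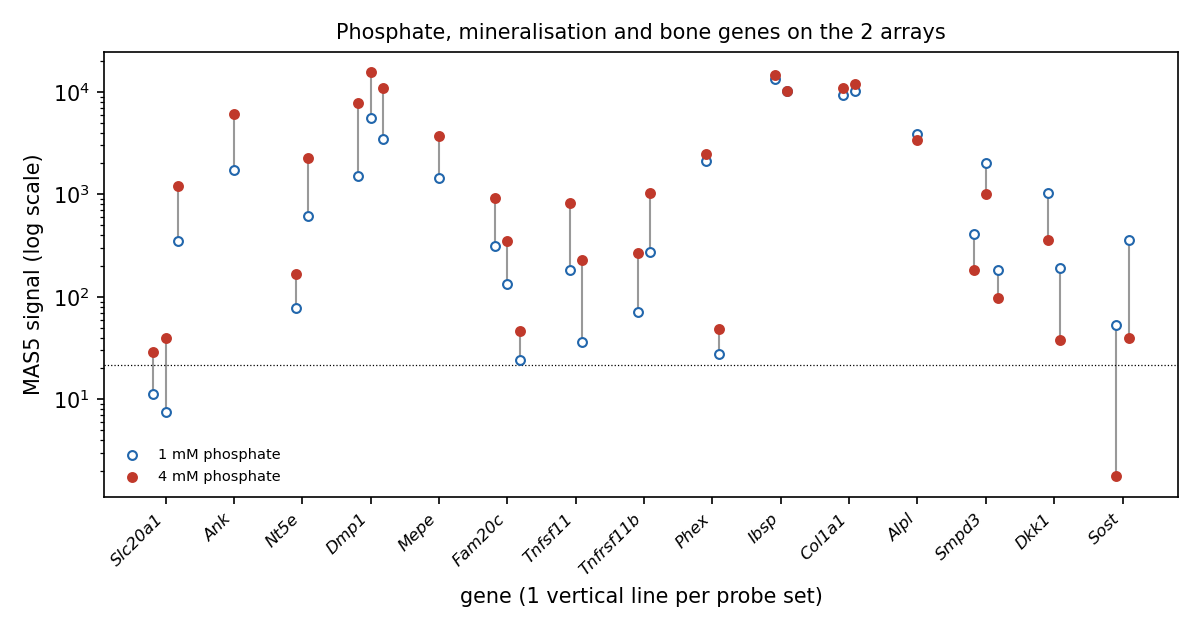
Each vertical line joins the MAS5 signals (log axis) of 1 probe set on the 1 mM phosphate array (open blue) and the 4 mM phosphate array (filled red) for 15 genes of phosphate handling, mineralisation and bone, and the dotted line marks the floor of 21.5. Dmp1 went from 5505 to 15708 on its main probe set and Sost from 359 to 39.9, and values under the dotted line are drawn as deposited.

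Genes of the oxidative stress and metal response had a median of 0.38 at percentile 100, or −0.08 with the poly-A spikes as reference. Of 21 measured members, 3 were at least 2-fold higher, none was 2-fold lower and 9 lay within 1.5-fold. The metal-binding metallothionein genes Mt2 and Mt1 were 6.85-fold and 4.47-fold higher, while Nqo1, a quinone reductase, was at −0.85. Glycolysis and hypoxia genes had a median of 0.36 at percentile 100, or −0.10 with the spikes as reference, and 5 of 29 were at least 2-fold higher. The highest were the glucose transporter gene Slc2a1 at 1.37 and the hexokinase gene Hk2 at 1.23. Car9, a carbonic anhydrase gene induced by hypoxia, was the lowest at −0.85.

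Matrix proteases and their inhibitors had a median of 0.30 at percentile 100. It was 0.19 with the floor at the pooled 65th percentile or at 100, 0.13 after quantile normalization, 0.16 after loess correction and −0.16 with the poly-A spikes as reference. Mmp3, encoding stromelysin-1, was 13.4-fold higher, whereas Mmp11 was at −1.10. In total 3 of 22 were at least 2-fold higher, 1 was lower and 13 lay within 1.5-fold. BMP and TGF-beta targets had a median of 0.23 at percentile 99.9, or 0.40 with every other floor tried and −0.23 with the spikes as reference, with 4 of 25 at least 2-fold higher and 2 lower. Inhba, the gene of the activin A subunit, was 8.08-fold higher, and the transcription factor genes Hey1 and Atoh8 were at −1.11 and −1.41. FGF ligands and receptors had a median of 0.28 at percentile 99.4, or 0.52 without a floor and −0.19 with the spikes as reference. Of 14 measured, 1 was at least 2-fold higher, none was 2-fold lower and 8 lay within 1.5-fold. The genes next to this median were dim, with signals of 39.2 or less on both arrays. The syndecan gene Sdc4 was highest at 1.01 and the receptor genes Fgfr2 and Fgfr3 were both at −0.67, with 0.17 on the dimmest probe set of Fgfr2 and −1.30 on that of Fgfr3.

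Wnt ligands, targets and inhibitors had a median of −0.31 at percentile 0.94, with 2 of 22 at least 2-fold lower and 1 higher. Dkk1 and Rspo2, which encodes a secreted Wnt agonist, were the lowest. Rspo2 had a log2 ratio of −1.59, its other probe set being at background, and Sfrp4, a secreted Wnt inhibitor gene, was highest at 1.48. The call ended under 5 alternatives, among them every other floor tried. Cell cycle genes had a median of −0.19 at percentile 1.67, and 37 of 39 lay within 1.5-fold. Their extremes were the cyclin D1 gene Ccnd1 at −0.85 and the replication licensing gene Mcm2 at 0.86, whose other probe set gave −0.28. With the floor at the pooled 65th percentile the cell cycle list was at percentile 2.57.

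Apart from Sost, the lowest genes above the floor on both arrays belonged to no single fixed list. Adh1, an alcohol dehydrogenase gene, had a log2 ratio of −2.90, and Cavin2, a structural gene of caveolae, −2.35 with a range of −2.42 to −2.14 over 3 probe sets. Nexn, which encodes an actin-binding protein, was at −2.21 and Zfp423, a zinc finger transcription factor gene, at −2.20. Rassf4, at −2.27, had another probe set at −0.15. Per3, a circadian clock gene, was at −1.82 on its brightest probe set, and its others lay close to or below the floor and give no direction. Lower genes were dimmer, with a median of the higher signal of 131 against 246 for higher genes.

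**Figure D3:**
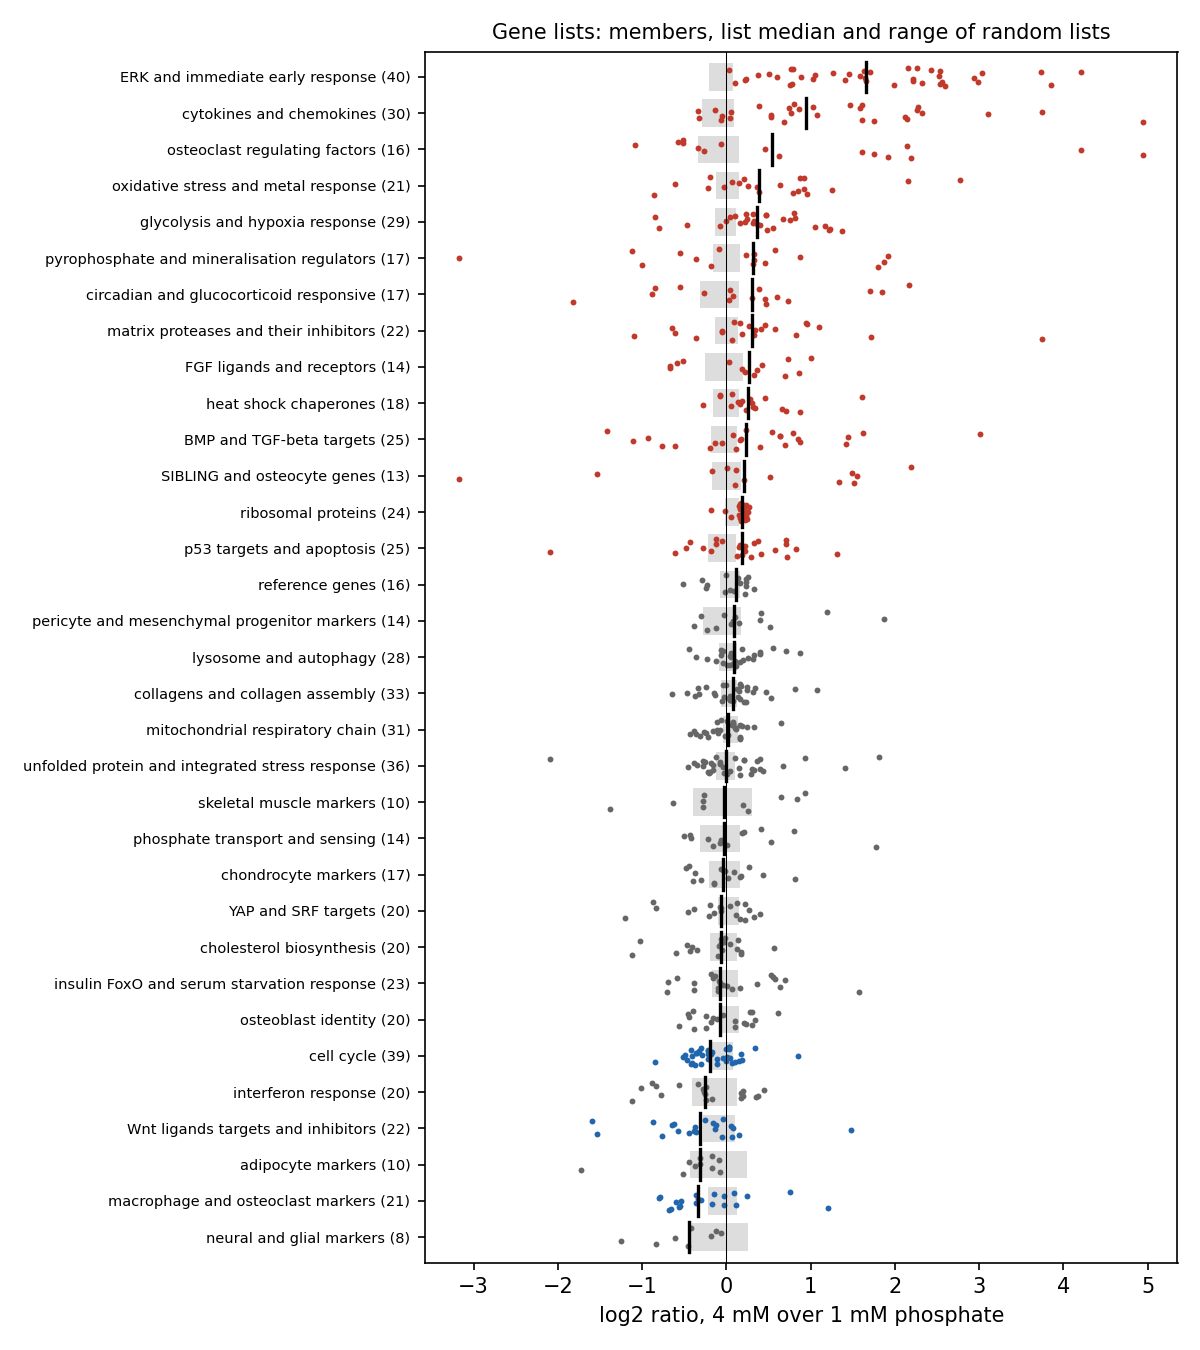
Each point is a measured member of 1 of the 33 lists with enough members, placed by its log2 ratio of 4 mM over 1 mM phosphate, black bars are list medians, and grey boxes hold the central 95% of medians of 10000 random lists of like signal. Red lists lay above and blue lists below the random lists, the ERK list is highest at 1.65, and with the poly-A spikes as reference all points and boxes would move by −0.46, which takes the medians of 11 of the 14 red lists below 0.

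Of the 33 lists with at least 4 measured members, 14 lay above and 3 below the central 95% of random lists. For lists of randomly drawn genes, 1.65 would lie outside. The lists share genes, such as Il6 and Ptgs2, so these counts are not independent of each other. Genes of a list can also vary together between cultures for any reason. The figure of 1.65 is therefore no measure of what cultures treated alike would give.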

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

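The 6 tests in this part, on spikes and on immediate early and cytokine genes, were chosen after the results they measure were seen.

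The manufacturer's spike probe sets, which enter no comparison of genes, differed between the arrays. The 24 probe sets for poly-A spikes, RNAs carried through labelling, were all brighter on the phosphate array, with a median log2 ratio of 0.46 (1.38-fold) and a range of 0.20 to 0.65. The 18 probe sets for hybridisation spikes, added after labelling, were also all brighter, with a median of 0.23 (1.17-fold). This median lay at percentile 99.8 of the medians of random sets of mouse probe sets of like signal. A trend with signal level was argued against, because the poly-A median of 0.46 lay above the range of −0.21 to 0.13 for mouse probe sets of like signal. Brighter hybridisation or staining as the whole cause was argued against, because the poly-A median exceeded that of the hybridisation spikes by 0.23. Random splits of the spike probe sets gave −0.13 to 0.15. These probe sets are repeated measurements of a few spike RNAs, so the splits measure spread between probe sets, not spread from pipetting or labelling. More spike per mouse mRNA, from pipetting or from less mRNA in the phosphate sample, stays open: the spikes stood 0.35 above the 16 reference genes, but array scaling fixes the average of the mouse genes and the spike amounts are not given in the sources used here.

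For the high immediate early and cytokine genes, noise of single probe sets was argued against, since other probe sets of 20 of these genes, not used for the gene values, had a median log2 ratio of 0.83 with 19 above 0, against −0.23 to 0.20 for probe sets of like signal. More macrophages in the phosphate culture was argued against, since the macrophage and osteoclast markers had a median of −0.33 with 5 of 21 above 0. Among markers with bright probe sets, Lyz2 and Ctsk had control signals of 7895 and 4097 and log2 ratios of −0.03 and 0.10, and Lyz1, on a probe set marked for cross-hybridisation, 10058 and 0.12. Ctss, Csf1r and C1qa had control signals of 1623, 1539 and 984 and log2 ratios of −0.36, −0.56 and −0.54, and 1 of the 21 markers, Ctsk, stands on another list. Handling of 1 culture, such as a medium change done differently, cannot be told apart from phosphate or its sodium with 1 array per group, and a response of osteoblasts or of other cells in the culture to phosphate stays a hypothesis.

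Probe sets without a single gene name in the annotation used entered no gene count. Of 1753 such probe sets above the floor on both arrays, 61 were at least 2-fold higher and 43 at least 2-fold lower in phosphate. The highest pair were 8.40-fold and 8.25-fold higher.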

How the results depend on the processing

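Chosen after seeing the data were the floor at 100, the poly-A spikes at 0, and lists without the immediate early and cytokine members or without members above the floor on 1 array only. Of 132 followed genes at least 2-fold different, 131 kept their sign under every alternative that gave a value. The exception was Per3, at 0.065 with the median of its probe sets. That value came from a probe set below the floor in the control and shows no direction. Changed floors, the pseudocount and the shift by the poly-A spikes cannot turn the sign of a 2-fold ratio, so the count of kept signs is weak support. Of 17 lists set apart, 11 were set apart on the same side of random lists under every alternative run. Centring on the median and the poly-A spikes at 0 move all genes alike, so they could not end such a call. Both the treatment of dim signals and the scaling moved the counts. Without a floor, 2126 genes were at least 2-fold higher and 1841 lower, against 279 and 358. The counts were 557 and 575 with the floor at the pooled 35th percentile, 183 and 164 at the 65th, and 156 and 119 at a signal of 100, and the pseudocount gave 216 and 171. The excess of lower genes thus turned in all of these but the 35th percentile, and loess gave 299 and 298. Genes with all probe sets at least 1.5-fold different, 169 higher and 163 lower, became 431 and 360 without a floor, 110 and 96 at the 65th percentile, and 98 and 74 at 100, and the pseudocount gave 104 lower. Higher floors leave fewer genes to count.

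With the poly-A spikes at 0, 129 genes were higher and 1727 lower, and 45 and 1135 by all probe sets, because every ratio moves by −0.46. List medians below 0 were then −0.15 for mineralisation, −0.25 for SIBLING and osteocyte genes, −0.19 for FGF, −0.16 for proteases, −0.23 for BMP and TGF-beta, −0.080 for oxidative stress, −0.28 for p53, −0.10 for glycolysis, −0.27 for ribosomal proteins, −0.21 for heat shock and −0.16 for circadian genes. The osteoclast regulating list, without members of the immediate early and cytokine lists, had a median of −0.16. Lists no longer set apart, with their medians, were Wnt without a floor (−0.16), at the 35th and 65th percentiles and at 100 (−0.21 each) and with the median of probe sets (−0.23), SIBLING at the 35th percentile (0.16), cell cycle at the 65th (−0.19), ribosomal proteins after quantile normalization (0.0070) and loess (0.033), and macrophage markers with the median of probe sets (−0.17). For these the cause was not tested. Of 16 lists not set apart, 3 were under at least 1 alternative, osteoblast identity, neural and skeletal muscle markers. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out.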

Other observations

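The tests of primary cilium, detoxification, CREB and NF-kB genes in this part were prompted by genes at the extremes of these data, and their lists left those genes out.

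Among genes of daily rhythm and glucocorticoid response, Sgk1, a kinase gene induced by glucocorticoids and osmotic stress, and Nfil3, a clock-linked repressor, were 4.49-fold and 3.61-fold higher in 4 mM phosphate. At the other end, the clock genes Per3 and Dbp were at −1.82 and −0.89, with −1.56 on the other probe set of Dbp. The list of 17, with 3 at least 2-fold higher and 1 at least 2-fold lower, had a median of 0.31 at percentile 99.9, which became 0.19 with the median of probe sets or without members above the floor on 1 array only, and −0.16 with the poly-A spikes as reference. Heat shock chaperones had a median of 0.26 at percentile 99.95, or −0.21 on the spike reference, led by Hspa4l, a relative of Hsp110, at 1.61, with 0.95 the lowest of its 5 probe sets. Targets of p53 had a median of 0.18 at percentile 99.7, or −0.28 on the spike reference, with 1 of 25 at least 2-fold higher, 1 at least 2-fold lower and 18 within 1.5-fold. The apoptosis gene Pmaip1 was at 1.31, and the stress-response gene Sesn2 was at least 4.27-fold lower, with 0.35 on its other probe set. Ribosomal protein genes had a median of 0.19 at percentile 99.8, with 0 of 24 at least 1.5-fold different, and were not set apart after quantile normalization (0.0070), while the spike reference gave −0.27. Outside the lists, Gch1, the first enzyme of tetrahydrobiopterin synthesis, was 8.07-fold higher. Tac1, the gene of substance P, and Has1, a hyaluronan synthase, were at least 13.6-fold and 5.90-fold higher.

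Several programmes were not set apart from random lists. Interferon response genes had a median of −0.25 at percentile 19.7, although Ifit1 and Usp18 were at −1.12 and −1.02. Unfolded protein and integrated stress response genes had a median of −0.01, a mean of 0.08 and percentile 49.5, with the transcription factor gene Cebpb at 1.82. Cholesterol biosynthesis had a median of −0.07 at percentile 33.1, with Mvk and Dhcr7, 2 enzymes of the pathway, at −1.12 and −1.02. The medians and percentiles were −0.06 and 6.69 for YAP and SRF targets, 0.02 and 25.3 for the respiratory chain (mean −0.0034), 0.09 and 86.3 for lysosome and autophagy, and −0.07 and 21.5 for insulin and FoxO genes (mean 0.07). Among other cell types, they were −0.04 and 38.1 for chondrocyte, −0.32 and 8.39 for adipocyte, −0.03 and 47.9 for skeletal muscle (mean 0.0053), 0.09 and 89.9 for pericyte and mesenchymal progenitor, and −0.44 and 2.65 for neural and glial markers. The adipocyte regulator gene Pparg was at −1.73 and S100b, listed here as a glial marker, at −1.25. All 17 chondrocyte markers were measured, some of them brightly, with control signals of 4029 for Cnmd and 2791 for Epyc. Which cells gave these signals was not tested. Reference genes had a median of 0.11 at percentile 84.9, or below 0 with the poly-A spikes as reference, since those stood 0.35 above them. Only 3 endothelial markers and 1 erythroid or mast cell marker were measured, too few to place.

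Lower expression of primary cilium genes was weighed as a hypothesis. The cilium is a sensory organelle of osteoblasts and osteocytes, and 49 of 54 measured genes of its assembly and transport had log2 ratios below 0, of which 5 were at least 2-fold lower, while 35 of the 54 lay within 1.5-fold. Their median of −0.45 lay below the range of −0.24 to 0.03 of random lists, with Cc2d2a, Ift172 and Ift88 at −1.33, −1.19 and −1.11. A trend with signal level was argued against as the whole cause, because the random lists were matched on signal. After a loess correction the median was −0.38, below −0.18 to 0.09. That correction shifts the list and its random lists nearly alike, so it adds little separate support. The group may be lower in this culture, while a difference between cultures unrelated to phosphate stays open with 1 array each.

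Enzymes of aldehyde and glutathione detoxification had a median of −0.40, with 19 of 20 below 0, 2 at least 2-fold lower, 15 within 1.5-fold, and random lists between −0.23 and 0.12. CREB targets had a median of 0.67, with 8 of 12 above 0, 4 at least 2-fold higher, 6 within 1.5-fold, and random lists between −0.35 and 0.20, and included Crem at 1.57. Genes of the NF-kB pathway had a median of 0.48, with 11 of 16 above 0, 3 at least 2-fold higher, 7 within 1.5-fold, and random lists between −0.37 and 0.16, led among genes above the floor on both arrays by Bcl3 at 1.73. With the poly-A spikes as reference, the CREB median became 0.21 and the NF-kB median 0.018, close to 0, while the cilium and detoxification medians became −0.91 and −0.86.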
